A study of Mus musculus with 6 samples.

How the data were processed

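The series holds 6 mouse RNA sequencing libraries, 3 from midbrain dopaminergic neurons given a scrambled hairpin and 3 from neurons given a hairpin against Satb1. Groups and replicate numbers were taken from the sample titles, which speak of siRNA, while the treatment text names hairpin constructs. The labels name the Dat bacTRAP line and total RNA but do not state a ribosome capture step, and libraries were prepared by standard Illumina methods, per the labels. The authors deposited 1 table of whole-number counts per gene with 1 column per library. TopHat2 2.0.8 and the genome build mm10 are named in the submitters' processing notes. The counting tool, its treatment of overlapping genes and of reads with several alignments, strand and read length are not given in the sources used here. The table has 23079 rows, of which 3361 had 0 counts in all libraries. Gene identifiers in the table are NCBI gene numbers, and 23008 of them matched the RefSeq gene table of GRCm38.p6, from which coordinates and current symbols came; symbols are given as in the deposited table.

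Several properties of such counts can affect the measurements. There were 13 genes with a mean of at least 100 counts whose counts were identical to those of another gene, so that some reads were counted for more than 1 gene. Exons of 33.8% of the tested genes overlap another annotated gene, and without strand their reads cannot be separated. Families of near-identical copies, such as histone and protocadherin genes, are uncertain for the same reason. Replicate libraries were compared by a chi-square per gene over genes with at least 20 counts in a pair, which lay between 58.5 and 156 where sampling noise alone gives about 1, so no library was a copy of another.

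The main test was the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3 on the deposited counts, with TMM scaling, filterByExpr by group at its minimum count of 10 and minimum total count of 15, and Benjamini-Hochberg adjustment over 16766 genes with a threshold of 0.05. The test, the samples, the alternatives, the gene lists and the rule for named genes were fixed before the data were examined. Standard errors of log2 fold changes were derived from the F statistic. CPM values were scaled with the TMM factors. The square root of the common dispersion was 0.276. Every gene was tested with 2 sides.

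Named genes were Satb1; the 10 higher and 10 lower genes with the largest log2 fold change among those called, with a mean of at least 2 CPM and no overlap between the groups; the 10 most abundant called genes without overlap; the called members of each gene list, at most the 4 with the smallest p, or else the 2 with the smallest p; and Th, Slc6a3, Slc18a2, Cdkn1a, Gfap and Aif1. Predicted models and pseudogenes were passed over, which removed 1 gene in each direction and none of the abundant genes. Some genes that this rule takes are not reported here, and they stay in the counts and tests of their lists. Other list members named in the text were chosen after their values were seen.

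There were 36 gene lists, covering dopamine neuron identity and its regional subtypes, other neurons, glia, vessels, ependyma, blood and lymphocytes, inflammation and interferon, p53 targets, cell cycle, apoptosis, stress responses, activity, respiration, ribosomes, synapses, channels, receptors, Parkinson disease genes, lysosomes, cholesterol synthesis, chromatin, axon guidance and neuropeptides. No symbol of the mitochondrial genome list matched a row of the table, and it was not analysed here. The 34 lists with at least 5 tested genes were compared with all other genes by camera in limma 3.58.1, on log2 CPM with a prior count of 2 and a preset correlation of 0.01, with adjustment over the lists. The sign of the median and of the mean differed for the lists of genes enriched in the ventral tegmental area and of chromatin organisers. Camera called 7 lists higher and 4 lower, and none of these held with an estimated correlation. Some genes belong to more than 1 list, such as Slc6a3, Kcnj6 and Sesn2.

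On simulated counts for 16766 genes, drawn from the means, library sizes and dispersions of the 6 libraries with 200 genes changed, the edgeR test recovered 30% of 100 genes changed 1.5-fold and 66% of 100 genes changed 2-fold, and called 5 unchanged genes. In the real data 3536 genes were called, and the adjustment depends on how many genes change. These shares are therefore not the recovery in the real data. In a second simulation camera called the 1 planted list and 0 others. Genes were drawn independently there, so it does not test false calls among correlated genes. In the real data the estimated correlation of the called lists lay between 0.012 and 0.451.

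Alternatives were other scalings (relative log expression and total counts), DESeq2 1.42.0, limma-voom, no low-count filter or a mean of at least 1 CPM, a robust dispersion, the replicate number as a block, a covariate from markers of 4 other cell types, other thresholds, other set tests, and leaving out each library. An offset for transcript length and GC content, a count without overlapping genes, and the called members of each list without each library and under each scaling were added after seeing the data. Words of 7 bases in 3' UTRs (GENCODE M21 transcripts) were scored with Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3: the ranks of log2 fold changes were adjusted for 3' UTR length, GC content, base composition and expression level, and 1000 shuffles of the genes gave the chance level. That search recovered 1 planted word in a test on simulated changes. Figures were drawn with matplotlib 3.10.9.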

Results

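RNA was profiled from midbrain dopaminergic neurons of C57BL/6 mice that carry the Dat bacTRAP transgene, which places a tagged ribosomal protein in cells expressing the dopamine transporter. Adeno-associated virus of serotype 1 delivered either a short hairpin RNA against Satb1 or a scrambled hairpin, each with EGFP as a marker. The substantia nigra pars compacta and the ventral tegmental area were dissected from 1 mm coronal slices. There were 3 control and 3 Satb1 knockdown libraries, and the labels give 3 mice aged 4 months for the 6 libraries without saying which library came from which mouse. The p-values measure only the spread between these libraries. The deposited gene counts summed to 170351145, 162101571 and 160792736 in control libraries 1 to 3 and 164554674, 147486754 and 151867516 in knockdown libraries 1 to 3, and 1 count corresponded to between 0.00557 and 0.00672 CPM, the unit of counts scaled to a common library size. Control libraries had a scaling factor from the trimmed mean of M-values (TMM) between 0.925 and 0.955, and knockdown libraries between 1.04 and 1.09.

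Satb1, a chromatin organiser that binds AT-rich DNA, was the target and was lower in every knockdown library. Its level was 351, 350 and 319.8 CPM in control libraries 1 to 3, and 82.9, 166 and 61.2 CPM in knockdown libraries 1 to 3. The mean fell from 340.2 ± 17.7 to 104 ± 55.5 CPM (SD, n = 3 each), a log2 fold change of -1.72 ± 0.26 (SE; edgeR quasi-likelihood test, adjusted p = 0.00106), or 3.29-fold. Satb1 (gene identifier 20230) lies on the minus strand of chromosome 17, from 51736187 to 51833290 in GRCm38, the assembly also called mm10. Its exons overlap those of the predicted genes Gm36931 on the same strand and Gm6934 on the opposite strand. Strand cannot separate reads of Satb1 from those of Gm36931 in shared exons. Reads of Gm6934 cannot be told apart where strand was not used in counting.

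**Figure D1:**
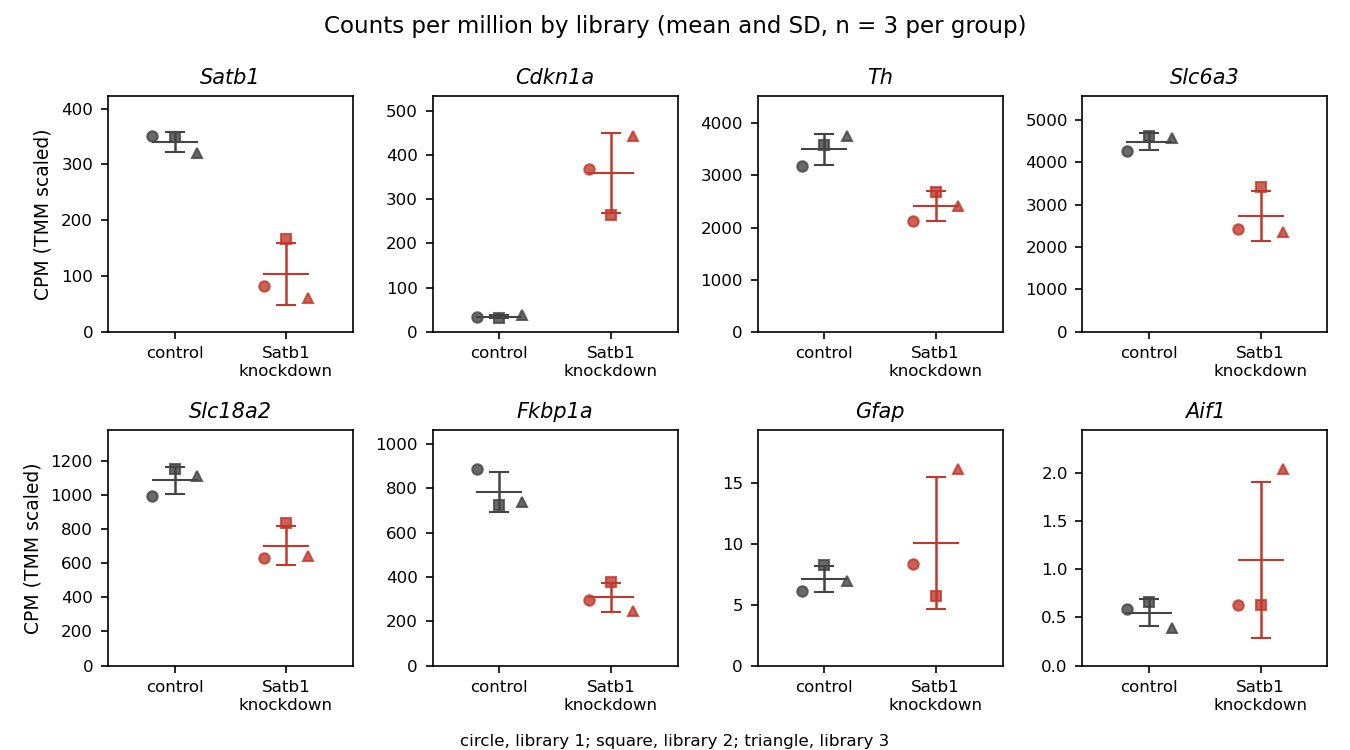
Each panel shows 1 gene, with TMM-scaled CPM on the vertical axis from 0 and the 2 groups on the horizontal axis; symbols are single libraries, and the bar and whiskers are the mean and SD of 3 libraries. Satb1 fell from 340.2 to 104 CPM and Cdkn1a rose from 34.2 to 359 CPM, while Gfap and Aif1 overlapped between the groups.

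The knockdown was compared with the control to find which transcripts change in dopaminergic neurons when Satb1 is reduced. Cdkn1a, which encodes the cyclin-dependent kinase inhibitor p21, rose 10.5-fold, from 34.2 ± 3.60 to 359 ± 90.0 CPM, with a log2 fold change of 3.39 ± 0.17 (SE; adjusted p = 4.31e-07). The linker histone gene Hist1h1c rose 12.1-fold, to 131 ± 30.8 CPM. Hmox1, the heme oxygenase of oxidative stress, rose 7.20-fold, and Tyrp1, a melanosome protein, rose 7.24-fold. Among called genes with a mean of at least 2 CPM and no overlap between the groups, and predicted models aside, Cyb5r2 had the largest log2 fold change, 4.80, from 0.159 to 4.49 CPM, and Dcxr, Otor, Swap70, Ccdc122 and the histone gene Hist2h3c2 rose between 4.78-fold and 5.94-fold. After Satb1, the largest decreases among genes named by the same rule were in Spink13 (log2 fold change -1.61), Bcat2 (-1.47), Yeats4 (-1.42), the cold-shock domain protein gene Ybx1 (-1.38), the translation initiation factor gene Eif2b1 (-1.37), Fkbp1a (-1.35), Ccdc6 (-1.34), the complex I subunit gene Ndufa8 (-1.33) and the tubulin gene Tube1 (-1.29). Fkbp1a, which encodes the immunophilin FKBP12, was the most abundant of these and went from 783 ± 88.5 to 307 ± 66.3 CPM. The call for Tube1 was lost without control library 1, control library 3 or knockdown library 1. Exons of Cyb5r2, Cdkn1a, Swap70, Ccdc122, Bcat2 and Tube1 overlap a gene on the opposite strand, so their values are uncertain.

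Of 16766 genes tested, 1421 were higher and 2115 lower in the knockdown at an adjusted p under 0.05, which is 21.1% of the genes. The called genes that rose had a median fold of 1.597 and a median level of 17.4 CPM, and those that fell a median fold of 1.43 and a median level of 67.9 CPM. At least 2-fold changes were found for 342 higher and 119 lower genes. All 3 knockdown libraries lay on 1 side of all 3 control libraries for 38.7% of the tested genes, where chance gives 10% for 3 against 3 libraries, both directions together. The split of the calls depended on the scaling: with total counts in place of TMM, 2770 genes were higher and 972 lower, so that 74.0% of the called genes were higher against 40.2%. The median log2 fold change of all tested genes moved from 0.01 to 0.18. Knockdown library 2 showed a smaller part of the change than the others: on genes called without it, the median part of the mean change of the other knockdown libraries was 0.601 for higher and 0.706 for lower genes, against at least 0.962 for libraries 1 and 3. Without control library 2 the counts were 910 higher and 1322 lower, and without knockdown library 1 they were 804 and 1132.

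**Figure D2:**
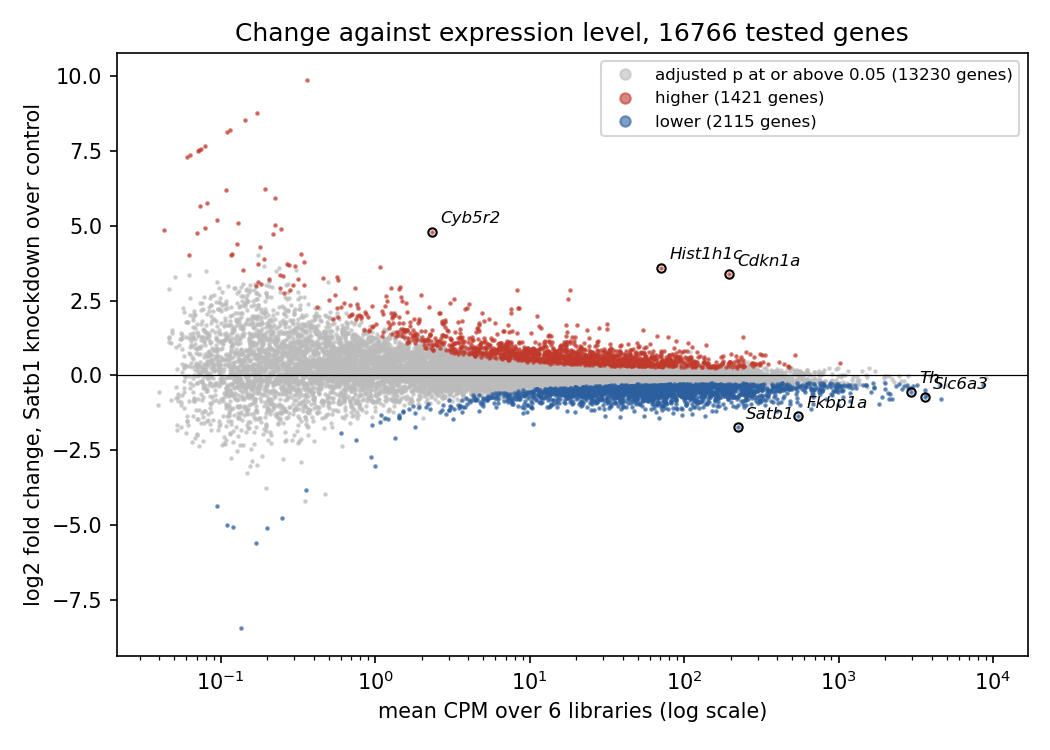
Every point is 1 of the 16766 tested genes, with the mean CPM over 6 libraries on a logarithmic horizontal axis and the log2 fold change of Satb1 knockdown over control on the vertical axis. The 1421 genes called higher and 2115 called lower are coloured, and the 7 circled genes are labelled.

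The most abundant of the changed genes were all lower. Snap25, a synaptic membrane fusion protein, went from 9562 ± 385 to 7731 ± 531 CPM (log2 fold change -0.31), and Aldh1a1, the retinaldehyde dehydrogenase of ventral-tier nigral neurons, from 5839 ± 741 to 3376 ± 530 CPM (-0.79). Vsnl1 (-0.67), Cplx1 (-0.50), Arf3 (-0.42), the cyclophilin gene Ppia (-0.34), the calmodulin gene Calm2 (-0.33) and Zc3h7a (-0.30) were also among the 10 most abundant called genes. The calls for Snap25, Calm2, Ppia and Zc3h7a were lost with total-count scaling, and that for Zc3h7a also without control library 2 or 3.

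Genes that define dopamine neurons fell as a group. Of 23 tested members of the dopamine neuron identity list, 13 fell, none rose and 10 did not pass the test; adjusted over the list alone, 16 were lower, and with total-count scaling 11 were lower and 1 higher. The dopamine transporter gene Slc6a3 fell from 4489 ± 193 to 2731 ± 586 CPM (log2 fold change -0.72 ± 0.12, SE; adjusted p = 0.00159). Th, the rate-limiting enzyme of dopamine synthesis, fell from 3507 ± 298 to 2410 ± 286 CPM (-0.54 ± 0.10; adjusted p = 0.00228), and Slc18a2, the vesicular monoamine transporter, from 1086 ± 79.2 to 703 ± 113 CPM (-0.63 ± 0.11; adjusted p = 0.00219). Gch1, which makes the cofactor of tyrosine hydroxylase, fell by 0.95 on the log2 scale, the potassium channel gene Kcnj6 by 0.94, Slc10a4 by 0.77, the transcription factor gene Pitx3 by 0.71 and Gucy2c by 0.60. The values of Nr4a2 (0.25), Lmx1b (0.17), Foxa1 (-0.08) and the autoreceptor gene Drd2 (-0.05) did not pass the test. The list was lower than other genes by camera with a preset correlation (adjusted p = 3.24e-05), a call not kept with an estimated correlation (adjusted p = 0.409). The median of the list against the control mean was -0.47, -0.30 and -0.50 in knockdown libraries 1 to 3, while in the same libraries the median was 0.74, 0.55 and 0.58 for oligodendrocyte markers, 0.95, 0.57 and 1.46 for microglia markers and 0.62, 0.44 and 0.40 for astrocyte markers. Of 15 genes enriched in the substantia nigra, 7 fell, among them Aldh1a7 (-1.14), Aldh1a1 and Atp2a3 (-0.83), and 2 rose, Fgf1 (0.79) and Cd24a (0.85); 7 and 2 passed when adjusted over the list alone. Of 17 genes enriched in the ventral tegmental area, Calb2 (0.61) and Cartpt (0.65) rose and Neurod6 (-0.67) and Tacr3 (-0.32) fell, with the same numbers adjusted over the list alone. The calls for the last 3 of these were each lost without at least 2 single libraries. With total-count scaling 2 genes of this list were higher and none lower, without control library 1 there was 1 higher and 4 were lower, and without control library 2 or knockdown library 1 edgeR called none lower. Neither regional list was called by camera (adjusted p = 0.156 and 0.672).

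Synaptic release genes were lower as a list. Of 35 tested, 20 fell, 1, Syn3, rose and 14 did not pass. Adjusted over the list alone, 22 were lower and 3 higher, and the same counts were called without knockdown library 2. The small GTPase gene Rab3a fell from 749.9 ± 18.7 to 375 ± 88.8 CPM, with a standard error of 0.13 for its log2 fold change, the calcium sensor gene Syt1 fell by 0.86 on the log2 scale, Cadps2 by 0.60 and Vamp2 by 0.57. The list was called lower by camera (adjusted p = 0.000105; adjusted p = 0.409 with an estimated correlation), and with total-count scaling 14 members were lower and 4 higher. Its median was -0.52, -0.26 and -0.35 in knockdown libraries 1 to 3, where that of oligodendrocyte markers was 0.74, 0.55 and 0.58 and that of microglia markers 0.95, 0.57 and 1.46. Among 42 pacemaker and calcium channel genes, 10 fell and 2 rose (13 and 5 adjusted over the list alone). The decreases included the SK3 channel gene Kcnn3 (-1.11), Kcnd3 (-0.99), its partner Kcnip3 (-0.94) and the sodium channel gene Scn2a1 (-0.64). Of 33 glutamate and GABA receptor genes, 7 fell and none rose, also when adjusted over the list alone, among them Gabra4 (-0.94). Of 52 axon guidance and adhesion genes, 11 fell, among them Nrxn3 (-0.84), Cdh8 (-0.84) and Ntn1 (-0.61), and 3 rose, with the same counts adjusted over the list alone. Among 23 axon injury response genes 6 fell, including Tubb3 (-0.95), Jun (-0.90) and Gap43 (-0.60), and 3 rose (7 and 3 adjusted over the list alone). These last 4 lists were not called by camera (adjusted p = 0.082, 0.0585, 0.2 and 0.358), and their medians changed sign with total-count scaling, from -0.10, -0.13, -0.07 and -0.04 to 0.07, 0.04, 0.10 and 0.12. With that scaling 6, 2, 6 and 5 of their members were lower and 6, 0, 11 and 3 higher, and fewer receptor genes were lower without control library 2 (3), control library 3 (4), knockdown library 1 (3) or knockdown library 3 (4). Axon guidance genes were lower in 6 cases without control library 2, control library 3 or knockdown library 1 and in 7 without knockdown library 3. No channel gene was higher in edgeR without control library 3 or knockdown library 1, and 1 axon injury gene was higher without knockdown library 1. Exons of Rab3a, Kcnd3, Gabra4, Nrxn3, Cdh8 and Jun overlap a gene on the opposite strand.

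Nuclear genes of oxidative phosphorylation and genes of cholesterol synthesis were lower as lists. Of 78 respiratory chain genes, 26 fell and 1 rose (32 and 1 adjusted over the list alone), with a median log2 fold change of -0.23, or -0.06 with total-count scaling. The complex I gene Ndufa8 fell 2.51-fold, the succinate dehydrogenase gene Sdhb fell by 0.55 and the ATP synthase gene Atp5d by 0.51 on the log2 scale, and the member that rose, Cox6a2, was at 0.160 CPM in controls and 2.001 CPM in the knockdown; its exons overlap those of Itgad on the opposite strand. Of 24 cholesterol synthesis genes, 12 fell and none rose (17 adjusted over the list alone): the regulator genes Srebf2 (-1.02) and Insig1 (-0.88), and Mvd (-0.75) and Hmgcs1 (-0.63), which encode enzymes of the mevalonate pathway. Both lists were called by camera (adjusted p = 2.31e-06 and 1.47e-05), and with an estimated correlation each had an adjusted p = 0.409. In knockdown libraries 1 to 3, where markers of oligodendrocytes and microglia were higher, the medians were -0.15, -0.19 and -0.27 for respiratory chain genes and -0.45, -0.21 and -0.46 for cholesterol genes. With total-count scaling 10 respiratory chain genes were lower and 4 higher, and 8 cholesterol genes were lower. Without control library 1 the lower respiratory chain genes were 15. The lower cholesterol genes were 7 without control library 2 and 8 without control library 3, knockdown library 1 or knockdown library 3. Of 21 genes of inherited Parkinson disease, 8 fell, including Pink1 (-0.46) and Atp13a2 (-0.42), and 1, Fbxo7, rose, with the same counts adjusted over the list alone. That list was not called (adjusted p = 0.0617), its median moved from -0.16 to 0.01 with total-count scaling, and 1 member was then lower, the call for Atp13a2 being lost. Without knockdown library 1, 3 members were lower. Without control library 2 or 3 it was 4, and without control library 1 or knockdown library 2, 5. No member was called higher by edgeR without control library 1 or knockdown library 1. Of 35 lysosome and autophagy genes, 7 rose, among them the cholesterol carrier gene Npc2 (1.04) and the lysosomal lipase gene Lipa (0.99), and 5 fell, including the autophagy genes Map1lc3a (-0.59) and Atg12 (-0.57); 8 and 5 passed when adjusted over the list alone. With total-count scaling 13 were higher and 4 lower, and camera made no call (adjusted p = 0.156).

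Targets of p53 and cell cycle inhibitors were higher as a list, with members in both directions. Of 26 tested, 11 rose and 4 fell (13 and 4 adjusted over the list alone). Besides Cdkn1a, those that rose included Sesn2 (log2 fold change 1.58), Bbc3 (1.49), a pro-apoptotic gene, Aen (1.27), Phlda3 (1.12) and Ccng1 (1.02), whereas Mdm2 (-0.37), the inhibitor of p53, Perp (-0.68), Cdkn2d (-0.38) and Rb1 (-0.34) fell. None of these 4 was called lower by edgeR with total-count scaling, where 13 members were higher, or without control library 2 or knockdown library 1, and 1 was without control library 1 or knockdown library 3 and 2 without control library 3. Trp53 itself was at -0.05 and did not pass. Camera called the list higher (adjusted p = 0.00231; adjusted p = 0.409 with an estimated correlation), and its median was 0.77, 0.53 and 0.99 in knockdown libraries 1 to 3. In the same libraries the median was 0.95, 0.57 and 1.46 for microglia markers and 0.74, 0.55 and 0.58 for oligodendrocyte markers. Of 29 apoptosis genes, 7 rose, including Apaf1 (1.04) and Bcl2l11 (0.73), and 4 fell, including Bad (-0.66). Among 33 genes of the unfolded protein and integrated stress responses, 11 rose and 3 fell. Those that rose included the serine synthesis genes Phgdh (2.09) and Psat1 (0.93), the folate enzyme gene Mthfd2 (1.09) and Chac1 (0.73), which degrades glutathione, while the chaperone genes Calr (-0.49) and Hyou1 (-0.42) fell. Of 28 heat shock and oxidative stress genes, 6 rose, among them Hmox1 and the glutathione synthesis gene Gclc (0.81), and 4 fell, among them Dnajb1 (-0.67) and Sod2 (-0.49). Of 25 cell cycle genes, Plk1 (-1.01), Aurka and E2f1 fell and Pcna (0.51), Rrm2 and Mcm5 rose. The call for Aurka was lost with total-count scaling and without control library 2, control library 3 or knockdown library 1, and that for Rrm2 without knockdown library 3. Without control library 2, control library 3 or knockdown library 1, 1 cell cycle gene was lower, and without knockdown library 3, 1 was higher. These 4 lists were not called by camera (adjusted p = 0.156, 0.0789, 0.282 and 0.173); adjusted over the list alone, the higher and lower members were 8 and 4, 11 and 3, 7 and 6, and 3 and 3. With total-count scaling they were 10 and 2, 12 and 1, 11 and 2, and 3 and 1. Without control library 3, 4 apoptosis genes were higher and 1 stress response gene was lower, 2 apoptosis genes were lower without control library 1 or 2, and 2 heat shock and oxidative stress genes were lower without knockdown library 1.

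Oligodendrocyte markers rose in the knockdown, and fewer markers of other cell types passed the test. Of 19 oligodendrocyte genes, 14 rose and none fell, also when adjusted over the list alone, including the myelin gene Mbp (85.7 ± 12.6 to 132 ± 16.6 CPM, log2 fold change 0.62). Camera called the list (adjusted p = 5.53e-06; adjusted p = 0.2496 with an estimated correlation), and 8 members were higher without control library 1 and 9 without knockdown library 1. Of 18 astrocyte genes, 5 rose, among them Aqp4 (0.63) and Gli3 (0.76), and 1, the glutamate transporter gene Slc1a2 (-0.47), fell, with the same counts adjusted over the list alone. Without control library 3, 2 astrocyte genes were higher, and without knockdown library 1 or 3, 1 and 3, while with total-count scaling 11 were higher and 1 lower. Of 25 microglia and macrophage genes, 4 rose, including Csf1r (1.45), Trem2 (1.95) and Cd68 (2.94), each under 3 CPM in all libraries, and 2 fell, among them P2ry12 (-0.45) (6 and 2 adjusted over the list alone). The exons of P2ry12 overlap those of Med12l, and those of Csf1r overlap Hmgxb3, both on the opposite strand. With total-count scaling 7 microglia genes were higher and none lower. Without knockdown library 1 edgeR called no microglia gene, without knockdown library 3 it called 1 higher and 1 lower, and without control library 1, 2 or 3 it called 2 higher. Of 19 genes of reactive astrocytes 3 rose, among them S1pr3 (1.11) and Steap4 (1.12), as when adjusted over the list alone. The astrocyte (adjusted p = 0.00503), microglia (0.00231) and reactive astrocyte (0.0489) lists were called higher by camera, and with an estimated correlation each had an adjusted p = 0.409. The microglia call was lost with genes of at least 1 mean CPM, and the reactive astrocyte call in 6 of 9 other settings. Knockdown library 3 stood apart in both, with medians of 1.46 for microglia and 1.19 for reactive astrocytes against 0.95 and 0.29 in library 1 and 0.57 and 0.20 in library 2. Gfap was at 7.13 ± 1.07 CPM in control and 10.1 ± 5.40 in knockdown libraries (adjusted p = 0.264), and Aif1 at 0.547 ± 0.141 and 1.10 ± 0.811 CPM (adjusted p = 0.258). Neither passed, and without knockdown library 3 the log2 fold change of Gfap was -0.0025 in place of 0.50. Among markers of other neurons, the cholinergic genes Chat (1.195) and Slc18a3 (1.18) rose out of 15 tested, and of 10 GABA neuron genes 1 rose, Pvalb (0.62), and 1 fell, with the same counts adjusted over each list alone; the calls for Slc18a3 and Pvalb were each lost in 4 of the 6 fits without 1 library. Oligodendrocyte precursor genes rose in 3 of 12, including Olig1 (0.75), ependyma and choroid plexus genes in 2 of 11, Ttr (2.61) and Rarres2 (0.51), and endothelium and pericyte genes in 1 of 21, Cdh5, whose call was lost in 4 of those fits, as when adjusted over each list alone. With total-count scaling 5 precursor genes and 3 GABA neuron genes were higher. Without control library 1, control library 2 or knockdown library 3, 1 precursor gene was higher, and the calls for Sox10 and Pdgfra were each lost in 4 such fits. None of these 5 lists was called by camera (adjusted p = 0.114, 0.156, 0.082, 0.176 and 0.0789, in this order).

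**Figure D3:**
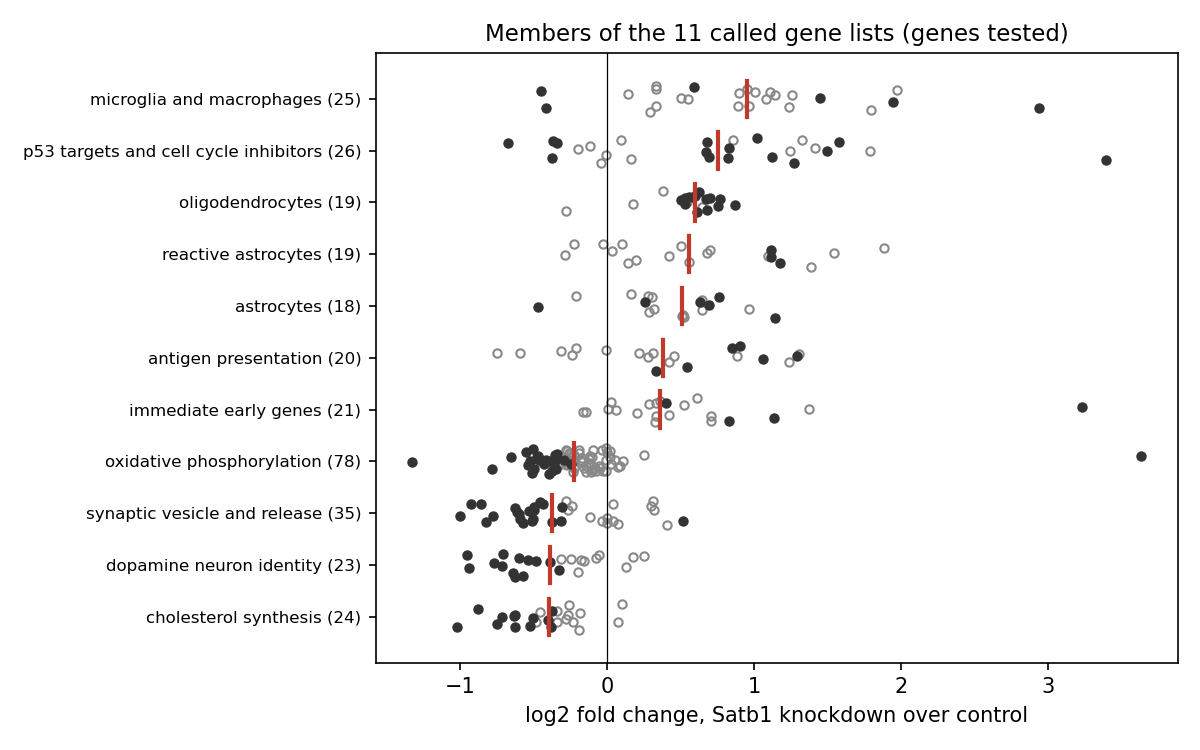
Each row is 1 of the 11 gene lists called by camera, with its number of tested genes in brackets and the log2 fold change of Satb1 knockdown over control on the horizontal axis. Filled points are genes with an adjusted p under 0.05, open points the other members, and the vertical bar is the median of the list, from -0.39 for cholesterol synthesis to 0.95 for microglia and macrophages.

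Of 20 antigen presentation genes, 6 rose and none fell, as when adjusted over the list alone, among them the class I light chain gene B2m (0.54) and H2-K1 (1.06). Of 21 immediate early genes 4 rose and none fell, as when adjusted over the list alone. Among them were Btg2 (0.83), which is also counted among the p53 targets above, and Fosl2 (1.13), while Fos was at 0.29 and did not pass. Both lists were called higher by camera (adjusted p = 0.0283 and 0.0183; each had an adjusted p = 0.409 with an estimated correlation), and each call was lost in 3 of 9 other settings. In knockdown libraries 1 to 3 the median was 0.55, 0.39 and 0.54 for antigen presentation genes and 0.15, 0.60 and 0.58 for immediate early genes, where it was 0.95, 0.57 and 1.46 for microglia markers and 0.74, 0.55 and 0.58 for oligodendrocyte markers. The median of immediate early genes was -0.31 in control library 1, against 0.20 and 0.07 in control libraries 2 and 3. Without knockdown library 1, 2 antigen presentation genes were higher, without control library 1 or knockdown library 3, 3, and without control library 2, 4; without knockdown library 3, 1 immediate early gene was higher, and without control library 1 or 2, 2. The call for Fosl2 was lost without knockdown library 3. No such call was made for interferon response genes (1 of 32 rose and 2 fell, as when adjusted over the list alone, adjusted p = 0.933), inflammatory cytokines and chemokines (2 of 24 rose, none adjusted over the list alone, adjusted p = 0.185), chromatin organisers (2 of 30 rose and 3 fell, as when adjusted over the list alone, adjusted p = 0.975), ribosomal proteins (2 of 83 rose and 2 fell, 1 and 1 adjusted over the list alone, adjusted p = 0.673) or lymphocyte genes (1 of 7 rose, as when adjusted over the list alone, adjusted p = 0.176). The chromatin genes included Hmgb2 (1.02) and Cux2 (-0.74), and the lymphocyte gene was Cd3d, which had no count in the control libraries and 0.128 ± 0.0874 CPM in the knockdown, a call lost without control library 1, control library 2 or knockdown library 2. With total-count scaling 15 ribosomal protein genes were higher and none lower, and 5 chromatin genes were higher and 2 lower. Without control library 2 or 3 no cytokine gene was called by edgeR. Without knockdown library 3, 6 ribosomal protein genes were higher. Interferon response genes were higher in 3 cases without control library 3, in 2 without control library 1 and in none in edgeR without control library 2 or knockdown library 3. They were lower in 1 case without control library 3 or knockdown library 3, and in none in edgeR without control library 1 or knockdown library 1. The haemoglobin gene Hba-a2 was at 6.74 ± 3.48 and 12.3 ± 5.97 CPM (adjusted p = 0.128), and none of 4 tested blood genes passed.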

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

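The offset for length and GC content, the count without overlapping genes and the list members by library and scaling were chosen after seeing the data. The log2 fold change of Satb1 stayed below 0 and called in every setting but the covariate of other cell types, between -1.43 and -2.24 with 1 library left out. With 1 library left out, 804 to 1356 genes were higher and 1132 to 2054 lower, and in every such fit the test had fewer samples. Total-count scaling called 2770 higher and 972 lower genes, and leaves out the TMM factors, which were 0.925 to 0.955 in control and 1.04 to 1.09 in knockdown libraries. Leaving out genes with overlapping exons left 936 and 1274 from fewer genes, and a minimum change of 2-fold, a stricter rule, left 342 and 119. DESeq2 called 2012 and 2376 genes, limma-voom 1462 and 2208, and the offset for length and GC content 1557 and 2072. No gene called in one direction was called in the other under any of these settings.

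The labels do not say that libraries with the same number share a mouse, and the correlations of their deviations from the group means were 0.056, 0.013 and 0.108. With the replicate block, 1924 genes were higher and 2789 lower, Satb1 was at -1.85, and 11 lists were called. The rule for pairing asked for a correlation above 0.1 for all 3 numbers, and 1 passed, so pairing was not taken. For 2 of 3 numbers the libraries were each other's best match, which is a weak hint from the data and not from the design.

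Of 135 called named genes other than Satb1, 99 kept the call without each of the 6 libraries and 36 lost it without at least 1, while 17 lost it under another setting apart from the covariate, all 17 with total-count scaling. The 11 list calls became 0 with an estimated correlation (1 list had an unadjusted p under 0.05), 17 with the directional and 31 with the mixed form of fry, and 9 to 13 with 1 library left out. The log2 fold change of Gfap was between -0.0025, without knockdown library 3, and 0.78, without knockdown library 2; the cause was not tested.

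The covariate from markers of other cell types left 0 higher and 0 lower genes in edgeR (306 had an unadjusted p under 0.05; no other tool was run with it) and 4 called lists. Its values separated the groups, from 1.34 to 1.40 in control and 1.87 to 2.12 in knockdown libraries, with a squared correlation of 0.944 with the group, so this fit says little about any gene. In it Satb1 was at 0.32, and 44 other named genes changed sign. The log2 fold changes that became positive were Bcat2 1.14, Tube1 0.011, Snap25 0.011, Aldh1a1 0.28, Vsnl1 0.057, Cplx1 0.0898, Slc6a3 0.40, Th 0.39, Gch1 0.033, Slc1a2 0.066, P2ry12 0.19, Stat2 0.29, Aurka 0.29, Tubb3 0.39, Rpl7l1 0.013, Syt1 0.18, Rab3a 0.021, Cadps2 0.0075, Gabra4 0.12, Dnajc13 0.085, Hmgcs1 0.27, Mvd 0.15, Insig1 0.082, Rad21 0.077, Nrxn3 0.053, Cdh8 0.0603, Ntn1 0.34, Ntrk2 0.32, Slc18a2 0.36. Those that became negative were Cartpt -0.73, Slc18a3 -0.042, S100b -0.29, Fa2h -0.14, Mbp -0.17, Olig1 -0.14, Ttr -0.35, Hba-a2 -1.26, Hbb-b1 -1.03, Ifih1 -0.20, B2m -0.24, Pcna -0.082, Rrm2 -0.43, Rps27l -0.35, Tacr1 -0.15.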

Other observations

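The tests of dilution, of knockdown library 2, of the 2-fold lower genes and of lower genes without a seed word, the word scores by library, and the families, were chosen after the results were seen. Mitochondrial ribosomal protein genes were in no list above. Grouped by symbol stem after seeing the data, 15 of 47 Mrpl genes and 13 of 29 Mrps genes, which encode mitochondrial ribosomal proteins, fell and none rose (camera, adjusted p = 0.00129 and 0.00198 over 185 families), as did 6 of 10 Tomm genes of the outer membrane import channel (0.0451), while the Timm genes of inner membrane import were not called, with 1 of 11 lower (0.807). The splicing factor families Srsf and Prpf had 5 of 11 and 5 of 13 genes lower (0.0261 and 0.0332), and 12 of 13 clustered protocadherin genes of the Pcdha family were lower (2.001e-05), which share their 3' exons and so their reads. The Kcnk family of leak potassium channels was the 1 called family with a higher median, with 3 of 11 genes risen (0.0328), and 7 of 11 Mtap and 4 of 14 Ndufa genes were lower (0.00336 and 0.0463), the Ndufa genes being also part of oxidative phosphorylation. With an estimated correlation each of the 9 called families had an adjusted p = 0.8804. The medians of the called families kept their sign with total-count scaling, but none of the Pcdha genes then passed, 4 Mrpl genes were lower and 3 higher, 3 Mrps, 3 Tomm, 2 Srsf and 4 Mtap genes were lower, and 3 Timm genes were higher.

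Neuropeptide and receptor genes moved in both directions. Of 37 tested, 6 rose and 3 fell, as when adjusted over the list alone, and camera made no call (adjusted p = 0.2). The neurotensin receptor gene Ntsr1 fell by 0.69 on the log2 scale and Ntrk2, the receptor of Bdnf, by 0.48, while the substance P receptor gene Tacr1 rose by 0.78, Crhr1 by 0.58 and the cholecystokinin receptor gene Cckbr by 1.19. With total-count scaling 8 were higher and 1 lower, and 3 were higher without control library 1 or 3. Without knockdown library 1, 2 were higher and 1 lower, and without control library 2, 1 was lower. The call for Ntrk2 was lost without control library 2 or knockdown library 1 and with total-count scaling.

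With 3 against 3 libraries there are 10 splits, too few for a share under 0.05. The real split called 1421 higher and 2115 lower genes and was the 1 split to do so, and the highest count of the other splits was 0 in edgeR, with at most 743 genes at an unadjusted p under 0.05. Every other split mixes control and knockdown libraries, so a group difference of any cause widens the spread within its groups. Their gene counts are therefore no measure of chance. For lists, 3 of the 10 splits called as many as the real one, 11 against at most 17. A length and GC trend is argued against as the whole cause of the lower genes, since 2072 genes were lower after the offset.

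A short word was in the 3' UTR of 158 of 2037 lower genes, or 7.76%. If the 460 genes that carry it were lower as often as genes without it (15.4%), 70.6 would be lower. A candidate explanation is that the Satb1 hairpin also acted on other transcripts through its seed. Among 16181 words of 7 bases, CAGACGT had the lowest score, -11.7, where 5% of shuffles went below -4.53, and 33 words passed that level; the highest score was 4.93, where 5% of shuffles went above 4.47, and 2 words passed; against the controls its score was -11.8, -10.2 and -11.0 in knockdown libraries 1 to 3, and 0.456, -0.391 and -0.268 for each control against the other controls. These values restate the pick of the word, but picked without the 96 genes lower by at least 2-fold it was the same word (score -11.3), and 10.4% of those 96 genes carried it against 3.57% of other genes (Fisher's exact test, 2-sided, p = 0.00245), among them Bcat2 and Eif2b1, while 7 of 10 Satb1 transcripts hold the word, which is not in the Satb1 3' UTR searched, a weak criterion as 46.1% of all words occur in Satb1 transcripts. Unlike the word scores, Fisher's test and the expected 70.6 were not adjusted for 3' UTR length, base composition or expression level. Direct silencing through CAGACGT is argued against for the 822 of 2037 lower genes that lacked both of its 6-base parts over their longest transcript. They are 40.4% of lower genes, against 52.0% of all genes searched. Other words below the 5% level of shuffles hold neither part, such as AACAGAC (-6.17) and CACAGAC (-5.89). Sites of that kind, and other transcripts of a gene, were not covered, so silencing through them stays open for the 822 genes. For the other lower genes direct silencing stays open. Of the 4 lists called lower, the synaptic list had 3 of 20 lower members with the whole word in the 3' UTR (Rab3c, Bsn and Cplx2). The dopamine identity, oxidative phosphorylation and cholesterol synthesis lists had none. Apoptosis, which was not called, had 2 of 4 (Cycs and Bcl2l1), and lower carriers in other lists included Slc1a2 and Ntrk2. Indirect effects of such silencing stay open beside an effect of Satb1 itself, as 1 hairpin was used and its sequence is not given in the sources used here.

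The lower dopamine identity genes may reflect fewer dopamine neuron transcripts in the RNA, a change in scaling or a change in the neurons. Scaling as the whole cause is argued against, since the median of the list was below 0 under each of 3 scalings. It was -0.39 with TMM, -0.38 with relative log expression and -0.22 with total counts, so its size depended on the scaling. Dilution by other cells would shift all transcripts made only in dopamine neurons by 1 factor. In the list, 7 of 23 genes lay over 3 standard errors from the weighted mean of -0.36. Gch1, Kcnj6 and Slc10a4 lay below it, and Foxa1, En2, Lmx1b and Nr4a2 above. Genes also made in the other cells would fall less under dilution. Whether the listed genes are made only in dopamine neurons was not tested, so this spread cannot decide on dilution as the whole cause. Dilution stays open, because the medians of oligodendrocyte (0.60), astrocyte (0.51), microglia (0.95), endothelium (0.38) and other neuron (0.51) markers were above 0. However, that of endothelium was 0.11 without knockdown library 1, 0.17 without control library 2 and -0.016 in knockdown library 3. For microglia it was 0.57 without knockdown library 3. For other neurons it was 0.30, 0.21 and 0.26 without control library 2, control library 3 and knockdown library 1. Such medians do not measure the share of RNA from other cells. Control means were 0.171 CPM for Cd68 and 85.7 CPM for Mbp, against 4489 CPM for Slc6a3. An effect of the knockdown on the neurons stays open as well.

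Knockdown library 2 showed a smaller part of the change, with 166 CPM of Satb1. On genes called without it, the median part of the mean change in the other libraries was 0.601 for risen and 0.706 for fallen genes, against at least 0.962 for libraries 1 and 3 on genes called without each. The choice of genes by the other libraries is argued against as the whole cause, since the smallest excess of libraries 1 and 3 over library 2 was 0.352. The size of that excess is uncertain, as the parts of libraries 1 and 3 were taken against a mean that includes library 2. Gene choice may still lower each part. A smaller share of affected neurons in that library may account for it, as the parts of risen and fallen genes differed by 0.105, and Satb1 and Cdkn1a showed parts of 0.648 and 0.619. A weaker knockdown in each neuron was not separated from a smaller share of affected neurons.

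Since Satb1 organises chromatin, neighbouring genes were tested for changing together. Over 11012 pairs of adjacent genes without overlap, the rank correlation across genes, which are not independent replicates, was 0.0432. It was above the 95% level of shuffles (0.0170), and 0 of 1000 shuffles were as large. After expression level was taken out it was 0.0432. The correlation was thus small but above that of shuffled genes. As it was below the minimum of 0.05 set before, the hypothesis was not borne out at the size named.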
